A study of Mus musculus with 39 samples.

How the data were processed

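RNA was measured by sequencing in 39 mouse libraries that the labels place in 10 groups. The animals of the labelling experiment carried Pax7-CreER, which is active in muscle stem cells (satellite cells), and a transgene for UPRT, an enzyme that lets a cell build the uracil analogue 4-thiouracil (4tU) into new RNA. Per the labels' protocols, labelled RNA was pulled down from the total RNA of hindlimb muscle after 4tU given in vivo, or from the total RNA of purified stem cells when 4tU was present during their isolation of about 6 h. Input was 500 pg of RNA for these libraries and 1 ng for the fixation libraries, which were extracted with a kit for fixed tissue. Reverse transcription was primed with oligo(dT), so polyadenylated RNA was read, and libraries were amplified for 13 to 15 cycles and sequenced as 101 bp paired reads. The labels give no batch and do not say whether replicates are separate animals, so the p-values measure only the spread between these samples, which may be technical.

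The values analysed are the authors' deposited RPKM (reads per kilobase of gene model, scaled to library size), in 1 table of 32 libraries and 16979 genes for labelling and inhibition and 1 table of 7 libraries and 13938 genes for fixation. Per the submitters' processing notes, Trim Galore, STAR, featureCounts from Subread and edgeR were used with the mm10 genome, and versions are not given in the sources used here. The header of the larger table is shifted by 1 cell against its values, and columns were taken by their position after that shift. In both tables the deposited RPKM of a gene, multiplied by its length and a factor for the library, came out as whole reads within 0.1 of a read, which gave the reads per library and the library scaling the authors had applied. The scaling factors ran from 0.612 to 1.95 in the larger table and from 0.903 to 1.01 in the fixation table. Of the genes the files give no symbol, 1350 of 1488 and 468 of 555 were named by gene ID from a GENCODE table. Coordinates are those of the files on mm10. The tables were normalised separately, so tests stayed within a table. No value column was left unused.

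The planned test for counts was replaced by the one planned for normalised values, because the unit was RPKM. The tests ran in limma 3.58.1 (R 4.3.3) on log2(RPKM + 0.5) of the libraries of the groups compared, with the trend option of its empirical Bayes step, over genes at 1 RPKM or more in at least 3 of those libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p printed for a gene comes from this limma fit. Fold changes are on the log2(RPKM + 0.5) scale, which understates changes of genes at low levels. Levels are group means of RPKM ± SD. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

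Chosen before the data were examined were the comparisons, 18 gene lists, the tests and the rule for naming genes. Lists of 5 or more tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01. The camera test compares a list with all other genes, so its sign can differ from that of the list's own median. Lists covered immediate early, heat shock, NF-kB and cytokine, satellite cell, Notch signalling, myogenic differentiation, cell cycle, muscle fibre, endothelial, fibro-adipogenic, immune, erythroid, smooth muscle and pericyte, Schwann and glia, tenocyte, ribosomal protein, mitochondrially encoded and nuclear oxidative phosphorylation genes. Some genes stand on more than 1 list, such as Notch3. Of the calls the preset correlation gave in 8 comparisons, only those of the fibro-adipogenic and immune lists in isolation-labelled RNA against total RNA held with a correlation estimated from the data. The fry test, which asks whether a list's genes move on balance one way and compares them with no other genes, was run beside it. Its results are not given here, so the list calls below are those of camera alone.

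The rule named, for each comparison, up to 8 genes with the largest rise and 8 with the largest fall among called genes at 5 RPKM or more in the higher group whose libraries did not overlap. It left unnamed gene models known by number, and allowed some of these genes to be left out; 3 genes are not reported here. It added up to 4 members of each list by adjusted p, and Pax7, Myf5, Myod1, Fos, Jun, Egr1, Hspa1a and Acta1 in every comparison. Gm10800, Mucl2 in single libraries and the markers given per library were singled out after their values were seen. Hspa1a and Hspa1b, the Hba and Hbb globin copies, and Mir6236 and Lars2, where reads of repeated sequence can be placed, are uncertain because similar copies can share reads. Strand use in the counting is not given in the sources used here.

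Each comparison was recomputed with library factors from the median of ratios, without the filter, with a filter of 50 reads, with limma-voom on the recovered reads, with all groups of a table in 1 fit, with the replicate number as a block, with pseudocounts of 0.1 and 1, and without each replicate in turn. The limma-voom fit used quality weights, which can give a library that stands apart less weight. Its results can therefore differ for that reason and not through the use of reads. For the inhibitor, library sizes from mitochondrially encoded genes were planned too, since RNA polymerase II does not transcribe them. Library sizes from all recovered reads, and tests without genes at least 2-fold higher in whole muscle than in isolated cells, were added after the data had been seen. In no comparison did every sample correlate best with its own replicate number, so the numbers were not taken as pairs. For the 4 d label against whole muscle and against isolated cells, 3 of 4 samples did.

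The pipeline was tested on simulated reads drawn for both groups from the means of the reference group, with the spread of each gene and the libraries' sizes. Noise was drawn for each gene on its own. A library that stands apart as a whole, as alpha-amanitin replicate 1 does, was not simulated. The shares and false calls below hold for that simpler setting. Of genes simulated with a 2-fold change, it recovered 46.3% for alpha-amanitin against DMSO, 32.8% for isolation-labelled against total RNA, 40.3% for 6 h against isolation label and 10.4% for fixed against unfixed cells, and 98.5% or more in the other 4 comparisons. With a 4-fold change these shares were 98.5%, 80.3%, 89.4%, 80.3% and 100%. Between 4 and 18 unchanged genes were called per comparison, among 10512 to 14338.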

Results

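Polyadenylated RNA of mouse hindlimb muscle and of its purified stem cells was sequenced in 39 libraries to compare what the stem cells transcribe in the animal with what they hold after isolation. Of 10 groups, 8 held 4 libraries each. They covered RNA labelled with 4-thiouracil for 6 h, 1 d or 4 d in vivo and pulled down from whole muscle, and RNA labelled during the isolation of the stem cells and pulled down from them. They also covered the total RNA of whole muscle, of isolated stem cells, and of stem cells isolated with alpha-amanitin, an inhibitor of RNA polymerase II, or with its solvent DMSO. The other 2 groups held stem cells from mice perfused with 1% paraformaldehyde before isolation (n = 4, replicates 1, 3, 4 and 5) and from unfixed controls (n = 3). Reads recovered from the RPKM values numbered 46839152 to 60883815 per library for the 1 d label, 40385703 to 65442116 for the 4 d label and 30933516 to 87375972 for the 6 h label. They numbered 2321903 to 7742378 for the isolation label, 41068178 to 102619074 for whole muscle and 15307952 to 22408295 for isolated cells. With alpha-amanitin they numbered 35417501 to 54214947, with DMSO 24189620 to 33255988, for fixed cells 22704011 to 25045404 and for unfixed cells 23734773 to 24930136. The isolation label thus had the fewest reads behind its values.

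Muscle fibre transcripts, which come from the mature tissue and not from stem cells, took 24.2 ± 0.215% of reads (SD, n = 4) in whole muscle. They took 26.8 ± 0.192% in the 1 d label, 26.2 ± 0.377% in the 4 d label and 14.7 ± 0.122% in the 6 h label. They took 0.235 ± 0.0566% in isolated cells and 0.154 ± 0.0146% with DMSO, but 2.86 ± 1.08% with alpha-amanitin and 7.51 ± 4.46% in the isolation label. Pax7, the transcription factor that marks satellite cells, stood at 17.9 ± 1.2 RPKM in isolated cells, 9.74 ± 3.10 in the isolation label and 0.0889 ± 0.0118 in whole muscle. In the labels given in vivo it stood at 0.318 ± 0.0581 RPKM for 6 h, 0.178 ± 0.0509 for 1 d and 0.196 ± 0.0453 for 4 d. Gm10800, a gene model of repeated sequence, took 13.0 to 17.5% of reads in the 6 h label, 2.99 to 5.93% in the isolation label, 2.08 to 3.39% with alpha-amanitin and 0.134 to 0.240% with DMSO. Alpha-amanitin replicate 1 correlated less with its group (mean r across genes 0.911) than the other 3 replicates did (0.967 to 0.969). No pair of libraries held identical values. Over genes of 20 to 200 reads, replicates of whole muscle differed little more than read sampling would make them (chi-square per gene 1.113 to 1.199). Over all genes of 20 reads or more they differed by more than that (2.488 to 8.146), and each was kept as a replicate.

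The first comparison asks whether the RNA of isolated stem cells changes when transcription is blocked during isolation. Among the largest rises with alpha-amanitin, Ckm, the muscle creatine kinase (chromosome 7, 19411094 to 19421583), stood at 1009 ± 509 RPKM against 5.10 ± 2.19 with DMSO (161-fold, adjusted p = 6.78e-05, n = 4 each). Acta1, skeletal muscle actin (chromosome 8, 123891767 to 123894736), stood at 4323 ± 2172 against 26.4 ± 9.42 RPKM (142-fold), and the myosin gene Myh4 and the carbonic anhydrase gene Car3 were 145-fold and 144-fold higher. The deepest falls were smaller. Cyp26b1, which degrades retinoic acid, fell 4.10-fold to 1.56 ± 0.549 RPKM, Ptgs2, the inducible cyclooxygenase, fell 4.06-fold to 4.30 ± 1.52, and the zinc finger genes Zim1 and Zfp146 fell 3.61-fold and 2.92-fold. Fos, known to respond within minutes to dissociation (chromosome 12, 85473890 to 85477273), stood at 1775 ± 674 against 2126 ± 378 RPKM (adjusted p = 0.357). Jun stood at 906 ± 337 against 948 ± 196 (0.705), and Egr1 at 2528 ± 637 against 2461 ± 270 (0.992). With library sizes from all reads Fos, Jun and Egr1 were lower (log2 change -0.87, -0.67 and -0.51, adjusted p = 0.00424, 0.0105 and 0.00253). So they were with library sizes from mitochondrially encoded genes (-1.98, -1.77 and -1.62), while Jun and Egr1 were higher under limma-voom (0.36 and 0.32).

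Of 13710 genes tested, 4646 were higher and 1412 lower with alpha-amanitin, 2151 and 441 of them by at least 2-fold, and the median of all genes was 0.28 on the log2 scale. Genes at least 2-fold higher in whole muscle than in isolated cells were 66.0% of the higher genes and 33.9% of those tested. Muscle fibre genes rose in 31 of 32 cases (32 adjusted over the list alone), with a list median 3.91 above that of all genes. Nuclear oxidative phosphorylation genes rose in 75 of 75, among them Cox6a2, the form found in heart and skeletal muscle, from 1.10 ± 0.523 to 141 ± 75.1 RPKM. Mitochondrially encoded genes, which RNA polymerase II does not transcribe, rose in 10 of 10, ND1 from 437 ± 144 to 1843 ± 522 RPKM. Ribosomal protein genes rose in 70 of 86 and fell in none (79 and 0 adjusted over the list alone), but their median turned lower when libraries were scaled to mitochondrially encoded genes. The same held for myogenic differentiation genes, which rose in 11 of 14 (12 over the list alone; Actc1 28.5-fold, Cdkn1c 4.73-fold). It held for fibro-adipogenic genes, which rose in 13 of 20 (14 over the list alone), and erythroid genes, which rose in 6 of 6. These 7 lists were called by camera, and none with an estimated correlation (adjusted p = 0.939 for each). The fibro-adipogenic call also ended without DMSO replicate 1 or 2 (adjusted p = 0.0602 and 0.0810), without muscle-enriched genes (0.543), under limma-voom (0.0525) and with library sizes from mitochondrially encoded genes (0.155). The erythroid call ended without DMSO replicate 1 (0.105) and under limma-voom (0.0518), and the ribosomal call with library sizes from mitochondrially encoded genes (0.279).

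The medians of the immediate early, heat shock and NF-kB lists turned lower when libraries were scaled to mitochondrially encoded genes. Those reference genes themselves took 0.991 ± 0.115% of reads with alpha-amanitin and 0.464 ± 0.0836% with DMSO, which lowers other genes under that scaling. Of 34 immediate early genes, whose median also turned lower with library sizes from all reads, 14 rose and 3 fell, with rises in Arc (3.34-fold), Klf4 (2.51-fold) and Cebpb (7.48-fold). As a list, however, they took a smaller share of reads with alpha-amanitin (4.70 ± 0.540%) than with DMSO (6.31 ± 0.247%). That share also fell for NF-kB genes (0.471 ± 0.0127 against 0.667 ± 0.0171%), but not for heat shock genes (6.21 ± 1.09 against 5.84 ± 0.358%). The call of Arc ended with library sizes from mitochondrially encoded genes (adjusted p = 0.242), and so did that of Klf4, whose sign turned (0.321). Of 18 heat shock genes 4 rose, among them Cryab, a small chaperone abundant in muscle (178 ± 46.0 to 703 ± 250 RPKM). Hspa1a stood at 2203 ± 979 against 1208 ± 313 RPKM (adjusted p = 0.143). It was higher without alpha-amanitin replicate 1 (adjusted p = 2.68e-05), under limma-voom (1.98e-13) and with all groups in 1 fit (0.00998), and lower with library sizes from mitochondrially encoded genes (log2 change -0.89, adjusted p = 0.00166). Among 23 NF-kB and cytokine genes 3 rose and 5 fell: Csf1 rose 2.19-fold, Rel fell 1.80-fold and Il6 fell 1.69-fold. The calls of Csf1 and, among satellite cell genes, Chrdl2 ended with library sizes from mitochondrially encoded genes (adjusted p = 0.0803 and 0.161), where their signs turned. The median of the NF-kB list was 0.18 and lay below that of all genes. Satellite cell genes rose in 4 and fell in 2 of 25 (3 and 1 over the list alone), with Chrdl2 up 2.39-fold and Megf10, a receptor of quiescent satellite cells, down 2-fold. The list median was above 0 on the authors' scale and below 0 under the 3 other scalings. Notch signalling genes rose in 4 and fell in 2 of 16, Notch2 and Rbpj, the DNA-binding partner of Notch, falling 2.06-fold and 2.03-fold. Pax7 stood at 22.8 ± 7.92 against 29.6 ± 5.60 RPKM (adjusted p = 0.226). It was lower with library sizes from all reads (log2 change -0.95, adjusted p = 6.81e-04), with those from mitochondrially encoded genes (-2.03, 1.01e-05) and with all groups in 1 fit (-0.44, 0.0497). Myf5 fell 1.56-fold (adjusted p = 0.0448), a call that ended without any 1 library except alpha-amanitin replicate 1 (0.0636 to 0.106) and without muscle-enriched genes (0.0618). Myod1 rose 1.86-fold (0.0280), a call that ended without alpha-amanitin replicate 2, 3 or 4 or DMSO replicate 2, 3 or 4 (0.0596 to 0.0868). That call also ended with library sizes from all reads (adjusted p = 0.0878), and its sign turned with those from mitochondrially encoded genes (log2 change -0.72, adjusted p = 0.00155). Cell cycle genes rose in 14 and fell in 1 of 24, endothelial genes in 7 and 1 of 22 and immune genes in 11 and 1 of 22. Smooth muscle and pericyte genes rose in 7 and fell in 1 of 14, Schwann and glia genes in 4 and 1 of 14 (6 and 1 over the list alone) and tenocyte genes in 5 and 1 of 10 (5 and 2 over the list alone). Camera called none of these 6 lists, although the immune list (adjusted p = 0.116) passed without alpha-amanitin replicate 1 (0.00829), without the filter (0.0207), with a filter of 50 reads (0.0236) and with all groups in 1 fit (0.0472). The cell cycle list passed without the filter (adjusted p = 0.0207), with a filter of 50 reads (0.0243) and without muscle-enriched genes (0.00162). The NF-kB list passed as lower with library sizes from all reads (0.0301) or from mitochondrially encoded genes (0.00598), and the satellite cell list with the latter (0.0146). The medians of the NF-kB, Notch, endothelial and smooth muscle lists turned lower with library sizes from all reads. Relative to the authors' scale, the median of all genes moved by -0.14 with median-of-ratios factors (4762 higher and 2243 lower) and by -0.46 with library sizes from all reads (3190 and 4206). It moved by -1.45 with library sizes from mitochondrially encoded genes (281 and 13269), where the medians of 15 of the 18 lists turned from higher to lower. Without alpha-amanitin replicate 1, 7367 genes were higher and 3293 lower. The counts fell to 2317 and 511, 2352 and 578, and 2432 and 730 without its replicates 2, 3 and 4, and to 2809 and 611, 2750 and 594, and 2912 and 648 without DMSO replicates 2, 3 and 4.

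**Figure D1:**
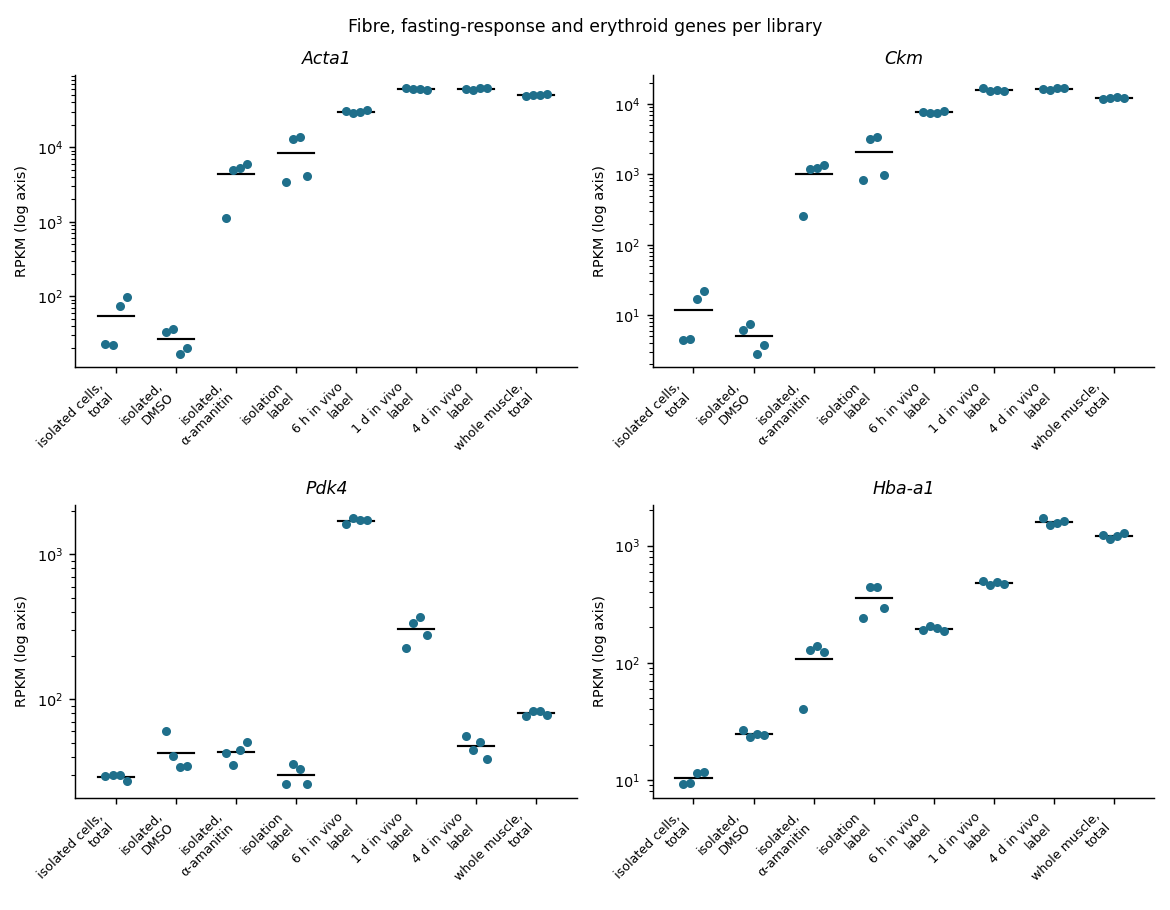
Levels of 3 genes of muscle tissue (Acta1, Ckm and Pdk4) and of the globin gene Hba-a1 in the 8 groups of the labelling and inhibitor experiment, in RPKM on a log axis; points are libraries and lines are group means. Acta1 lies between 1132 and 5979 RPKM in the alpha-amanitin libraries and between 16.8 and 35.8 in the DMSO libraries.

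The next comparison asks which RNA is made while stem cells are being isolated, by setting RNA labelled during isolation against the total RNA of the isolated cells. Muscle fibre genes took 3.55 to 11.8% of reads in the labelled libraries. Acta1 stood at 3420, 12818, 13575 and 4084 RPKM in replicates 1 to 4. Unlabelled RNA of muscle or blood carried through the pull-down was not tested for. A rise therefore need not mean synthesis during isolation, nor a fall its absence. In the labelled RNA Hbb-b1, a beta globin (chromosome 7, 103826534 to 103828096), stood at 368 ± 81.0 against 15.3 ± 0.634 RPKM (22.9-fold, adjusted p = 8.66e-08, n = 4 each). Lyz2, the lysozyme of macrophages, stood at 273 ± 48.8 against 12.8 ± 0.499 (20.3-fold), and Acta1 at 8474 ± 5468 against 54.0 ± 37.6 (158-fold). Myog, a regulator of muscle differentiation, stood at 62.4 ± 18.3 against 7.26 ± 0.391 RPKM (7.80-fold), and Cdkn1c, a cell cycle inhibitor, was 7.99-fold higher. Of the satellite cell list, Pax7 (chromosome 4, 139737062 to 139833528) fell 1.85-fold, Myf5 2.44-fold, Calcr 2.70-fold and Megf10 3.03-fold. The induced genes Fos, Jun and Egr1 were also lower in the labelled than in the total RNA, by 1.70-fold, 1.65-fold and 1.93-fold. Myod1 (102 ± 24.6 against 93.7 ± 11.3 RPKM) and Hspa1a (738 ± 156 against 736 ± 40) did not pass the test, and with library sizes from all reads both were lower (log2 change -0.60 and -0.72, adjusted p = 0.0258 and 0.00775).

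In all, 4426 genes were higher and 4417 lower of 14863 tested, 3450 and 2324 by at least 2-fold. Fibro-adipogenic genes were higher in 16 and lower in 3 of 20 (Ly6a 14-fold, Dcn 7.53-fold) and immune genes in 19 and 1 of 21 (C1qb 18.4-fold). Both calls held with an estimated correlation (adjusted p = 0.0352 each), although the fibro-adipogenic call ended when muscle-enriched genes were left out (0.312). The other calls did not hold. Muscle fibre genes were higher in 31 and lower in 1 of 32 (adjusted p = 0.306 with an estimated correlation) and endothelial genes in 13 and 2 of 21 (14 and 2 over the list alone; 0.306; Fabp4, a lipid carrier, 15.6-fold). Erythroid genes were higher in 6 of 6 (adjusted p = 0.237). Ribosomal protein genes were higher in 84 and lower in 1 of 86 (adjusted p = 0.263; Rps27l 10.2-fold) and mitochondrially encoded genes in 11 of 11 (0.306; ND2 10.6-fold). Oxidative phosphorylation genes were higher in 74 of 75 (adjusted p = 0.263; Cox7c 19.9-fold) and myogenic differentiation genes in 10 with 1 lower of 14 (0.0895). Satellite cell genes were lower in 17 and higher in 2 of 25 (0.519), a call that ended without muscle-enriched genes (0.125). Immediate early genes went both ways, 11 higher and 15 lower of 34 (11 and 16 over the list alone), with a median of -0.43 and a mean of 0.06. Gadd45g (6.83-fold), Gadd45b (3.94-fold) and Jund (3.81-fold) were higher and Egr2 lower (3.01-fold). Of 18 heat shock genes 5 were higher, such as Hspb1 (10-fold) and Cryab (6.32-fold), and 10 lower, such as Hsph1 (2.50-fold). Of 23 NF-kB and cytokine genes 5 were higher, such as Nfkbia (2.72-fold) and Ccl2 (2.50-fold), and 8 lower, such as Birc3 (3.11-fold). Notch signalling genes were lower in 10 and higher in 3 of 16 (Notch3 2.88-fold and Rbpj 2.67-fold lower). Cell cycle genes were higher in 9 and lower in 4 of 24 and smooth muscle and pericyte genes in 6 and 3 of 13 (7 and 3 over the list alone). Higher and lower were Schwann and glia genes in 5 and 2 of 12 and tenocyte genes in 7 and 3 of 10. None of these was called as a list. The Notch list (adjusted p = 0.0536) passed without total RNA replicate 1, 2 or 3 (0.0396, 0.0499 and 0.0490) or isolation label replicate 3 or 4 (0.0314 and 0.00763), and without the filter (0.0430), with all groups in 1 fit (0.0351) or with a pseudocount of 1 (0.0425). The smooth muscle list passed without the filter (adjusted p = 0.0430) or with a filter of 50 reads (0.0336), the tenocyte list with library sizes from all reads (0.0311) and the cell cycle list without muscle-enriched genes (0.00503). With library sizes from all reads the median of all genes moved by -0.60, 2974 genes were higher and 7678 lower, and the medians of the cell cycle and Schwann lists turned negative, as did that of the smooth muscle list (-0.01), which then had 12 genes tested and not 13. Without muscle-enriched genes, 1174 were higher and 4297 lower. Those genes were picked partly for low levels in the same isolated-cell libraries that serve as reference here. Leaving them out removes rises by selection, so these counts, and list calls that changed without those genes, are no separate test.

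To compare transcription in the animal with transcription during isolation, the 6 h label given in vivo was set against the isolation label. The in vivo label was taken from whole muscle and the isolation label from purified cells, so tissue and setting change together. Egr1, which many stresses induce (chromosome 18, 34859823 to 34864984), stood at 4.76 ± 0.396 against 552 ± 196 RPKM (101-fold lower, adjusted p = 8.93e-08, n = 4 each). Hspa1a, the inducible HSP70, stood at 3.57 ± 0.251 against 738 ± 156 (179-fold), Fosb at 0.355 ± 0.0815 against 158 ± 50.6 (180-fold) and the chemokine gene Cxcl1 at 3.66 ± 0.334 against 777 ± 270 (180-fold). The neuropeptide genes Nppc and Gal were 307-fold and 274-fold lower. Among the largest rises in vivo, Pdk4, a brake on glucose oxidation (chromosome 6, 5483351 to 5496309), stood at 1711 ± 70.3 against 30.2 ± 4.90 RPKM (56.3-fold), and Pck1, Ucp3 and Ppp1r3c were 51.7-fold, 45.8-fold and 29-fold higher. Fos fell 32.3-fold, Junb 38.8-fold and Ier2 17.7-fold, while Jun stood at 218 ± 13.9 against 260 ± 77.0 RPKM (adjusted p = 0.346, and 0.0104 with library sizes from all reads, log2 change -0.77). Myf5 was 3.16-fold lower and Acta1 4.26-fold higher.

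Of 13003 genes tested, 5010 were higher and 3178 lower in the 6 h label, 2886 and 2257 by at least 2-fold. Immediate early genes were lower in 27 and higher in 3 of 34 (adjusted p = 0.282 with an estimated correlation). Heat shock genes were lower in 15 and higher in 2 of 18 (adjusted p = 0.194; Dnajb1 129-fold lower) and NF-kB and cytokine genes in 19 and 1 of 23 (20 and 1 over the list alone; 0.194; Ccl2 18.7-fold lower). Satellite cell genes were lower in 19 and higher in 2 of 25 (0.194), with falls in Pax7 (12.1-fold), Chrdl2 (43.6-fold), Cdh15 (13.9-fold) and Calcr (10.3-fold). Ribosomal protein genes were lower in 81 and higher in 2 of 86 (adjusted p = 0.194; Rps23 9.82-fold lower). Notch signalling genes fell in 9 and rose in 1 of 16 (adjusted p = 0.414; Notch3 10.7-fold lower) and cell cycle genes in 9 and 1 of 21 (0.194). Lower with none higher were fibro-adipogenic genes in 10 of 20 (adjusted p = 0.157), erythroid genes in 4 of 6 (0.360) and Schwann and glia genes in 8 of 11 (0.194). Muscle fibre genes were higher in 24 of 32 (26 over the list alone; adjusted p = 0.587; Ttn 5.02-fold and Ryr1 4.40-fold) and mitochondrially encoded genes in 9 of 12 (0.434; ND6 5.14-fold). Camera called neither the myogenic differentiation list (4 higher and 8 lower of 14; Myod1 8.32-fold lower) nor the tenocyte list (0 and 3 of 8) nor the smooth muscle list (4 and 6 of 14; Acta2 11.5-fold lower). Nor did it call the endothelial list (5 and 7 of 21, with a median of 0.02 and a mean of -0.22), the immune list (7 and 5 of 22) or the oxidative phosphorylation list (31 and 5 of 75; 27 and 5 over the list alone). Without isolation label replicate 2, 3 or 4 the myogenic differentiation list passed (adjusted p = 0.0470, 0.0407 and 0.0480), without replicate 2 or 3 the oxidative phosphorylation list (0.0470 and 0.0327) and without replicate 1 or 3 the tenocyte list (0.0234 and 0.0407). The oxidative phosphorylation list passed without the filter (adjusted p = 0.00658), and the myogenic differentiation and smooth muscle lists with a filter of 50 reads (0.0226 and 0.0382). The erythroid call ended with all groups in 1 fit (0.0619). With library sizes from all reads the median of all genes moved by -0.50, 2558 genes were higher and 4883 lower, and the medians of the endothelial, immune and oxidative phosphorylation lists turned negative, the endothelial one also with median-of-ratios factors.

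**Figure D2:**
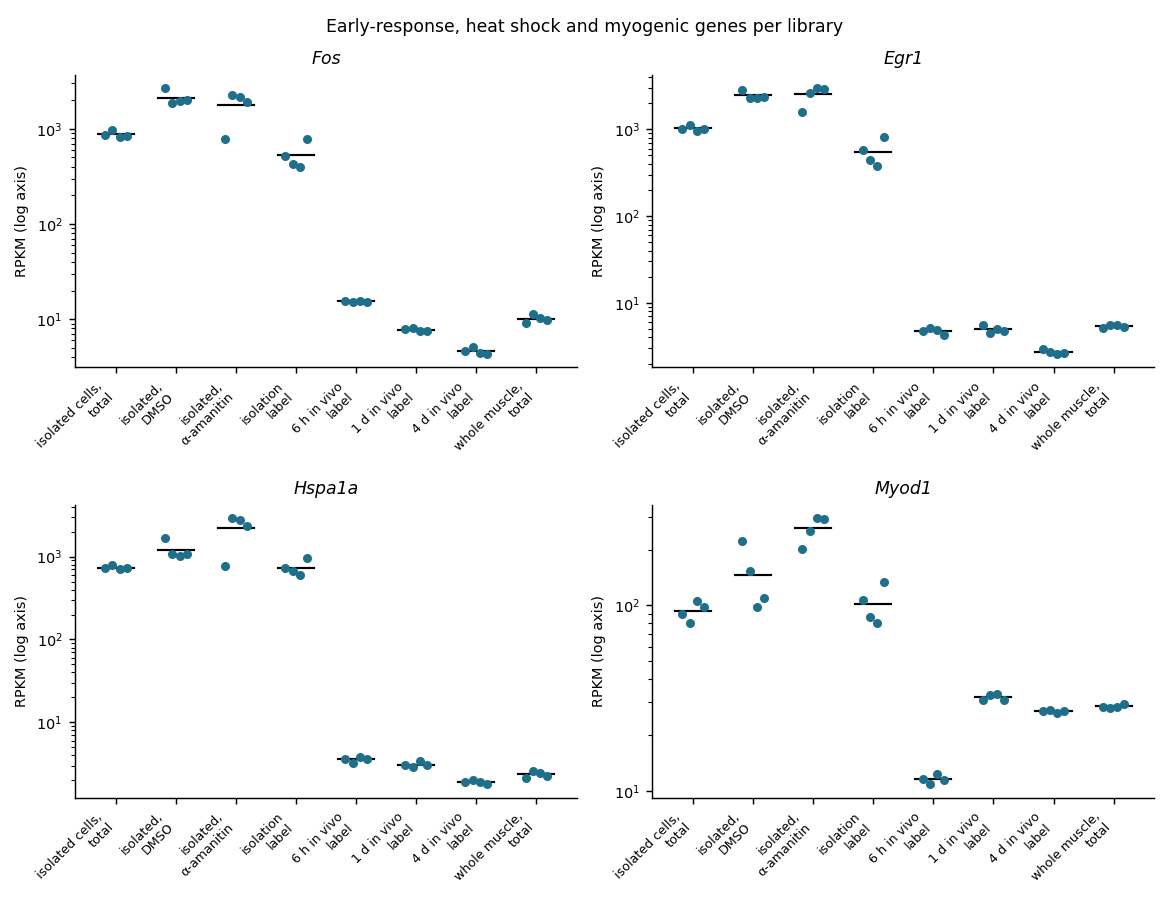
Levels of Fos, Egr1, Hspa1a and Myod1 in the 8 groups of the labelling and inhibitor experiment, in RPKM on a log axis; points are libraries and lines are group means. Egr1 averages 1023 RPKM in isolated cells and 552 in the isolation label, against 4.76, 4.98 and 2.72 in the 6 h, 1 d and 4 d labels given in vivo.

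How far the label given over 4 d stands apart from the muscle it was pulled from was tested against the total RNA of whole muscle. The profiles were close (r of mean levels across genes 0.955, genes not being independent replicates). Ribosomal protein genes were higher in the label in 78 and lower in 3 of 86, Rps12 (chromosome 10, 23785211 to 23787195) by 3.97-fold (180 ± 5.58 against 45 ± 2.41 RPKM, adjusted p = 6.92e-12, n = 4 each) and Rps21 by 2.92-fold. Immune genes were lower in 20 of 22, Lyz2 by 2.10-fold and Ctss, a protease of antigen-presenting cells, by 2.16-fold. Both lists were called by camera and neither with an estimated correlation (adjusted p = 0.871 for each). Scd1, a desaturase of fat synthesis, fell 4.51-fold (97.9 ± 4.03 against 443 ± 21 RPKM), Myot, a sarcomere gene, 4.06-fold and the myogenic factor Myf6 2.41-fold. Capn1, a calcium-dependent protease, and Cenpb, a centromere protein, were 4.44-fold and 4.26-fold higher. Mir6236 and Lars2 were 19.3-fold and 8.51-fold higher, and both can take up reads of repeated sequence.

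Of 11347 genes tested, 3189 were higher and 6397 lower, 571 and 607 by at least 2-fold, and the median of all genes was -0.21. Satellite cell genes split into 9 higher and 7 lower of 21, with Notch3 2-fold and Fgfr1 1.48-fold higher and Cd34 1.81-fold lower, and Pax7, at 0.196 ± 0.0453 against 0.0889 ± 0.0118 RPKM, was under the level needed for a test. The list median was -0.02, above that of all genes, and turned positive with median-of-ratios factors and with library sizes from all reads. Heat shock genes were lower in 15 and higher in 2 of 18 (Hspa5 2.14-fold, Hspd1 2.13-fold), with a camera adjusted p of 0.101, and passed without the filter (8.67e-04) or with a filter of 50 reads (0.0190). Immediate early genes were higher in 9 and lower in 11 of 27 (Dusp1 2.68-fold, Fos 2.08-fold and Egr1 1.83-fold lower) and NF-kB and cytokine genes in 5 and 10 of 18 (Ccl2 2.69-fold lower). Notch signalling genes were higher and lower in 6 and 4 of 13, myogenic differentiation genes in 2 and 8 of 13, cell cycle genes in 2 and 8 of 14. Muscle fibre genes were higher in 10 and lower in 17 of 32, with Ryr1 2.59-fold higher and Actn3 1.59-fold lower. Endothelial genes were higher in 7 and lower in 10 of 20, fibro-adipogenic genes in 4 and 12 of 20 (Lum 3.08-fold lower), erythroid genes in 4 and 1 of 6. Smooth muscle genes were higher in 4 and lower in 8 of 14 (median -0.16, mean 0.02), Schwann genes in 1 and 5 of 9, tenocyte genes in 2 and 5 of 8. Mitochondrially encoded genes were higher and lower in 5 and 6 of 12 and oxidative phosphorylation genes in 14 and 50 of 75. Camera called none of these, and gave the immediate early, satellite cell, fibre, endothelial, smooth muscle and mitochondrial lists an upward sign although their medians were below 0. The oxidative phosphorylation list passed without the filter (adjusted p = 8.67e-04). With all groups in 1 fit 1883 genes were higher and 4154 lower, and the call of Actn3 ended (adjusted p = 0.118). With library sizes from all reads the median of all genes moved by 0.18, 4569 genes were higher and 4990 lower, and the medians of the immediate early, fibre, endothelial and smooth muscle lists turned positive. Myod1, at 26.9 ± 0.379 against 28.5 ± 0.499 RPKM, fell 1.06-fold (adjusted p = 0.0279), a call that ended without 4 d replicate 3 (0.0775) or whole-muscle replicate 4 (0.0721). It also ended with median-of-ratios factors (adjusted p = 0.133), with all groups in 1 fit (0.721) and with the fibre, mitochondrial and erythroid lists left out of the normalization (0.130), and its sign turned with library sizes from all reads (log2 change 0.11, adjusted p = 0.00533). Jun fell 1.55-fold, while Myf5 (1.26 ± 0.434 against 1.58 ± 0.0316 RPKM) did not pass the test (adjusted p = 0.112). Hspa1a fell 1.19-fold and Acta1 rose 1.21-fold, and with all groups in 1 fit neither passed (adjusted p = 0.395 and 0.633), nor did Hspa1a with library sizes from all reads (0.175).

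The 4 d label was also set against the total RNA of isolated stem cells, where tissue and label change together. Egr1 stood at 2.72 ± 0.143 against 1023 ± 61.2 RPKM (317-fold lower, adjusted p = 3.77e-16, n = 4 each), Hspa1a was 306-fold, Fosb 418-fold, Fos 171-fold and Cxcl1 375-fold lower. Fam132b, which encodes erythroferrone (chromosome 1, 91366430 to 91374216), fell 675-fold from 724 ± 22 to 0.582 ± 0.167 RPKM. Jun was 9.16-fold and Myod1 3.42-fold lower. Pax7 was 26.4-fold lower, Myf5 44.5-fold, Chrdl2 133-fold and Fgfr4 62.5-fold. Ckm was 1649-fold, Pvalb, a calcium buffer of fast fibres, 1381-fold and Acta1 1366-fold higher. Of 14845 genes, 6465 were higher and 7566 lower, 4111 and 4622 by at least 2-fold.

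Among the lists of that comparison, immediate early genes were lower in 30 and higher in 4 of 34 (adjusted p = 0.161 with an estimated correlation) and heat shock genes in 15 and 3 of 18 (0.263; Dnajb1 146-fold). Lower and higher were NF-kB and cytokine genes in 20 and 1 of 21 (adjusted p = 0.0615; Vcam1 40.5-fold), satellite cell genes in 24 and 2 of 26 (0.0615) and Notch signalling genes in 13 and 3 of 16 (0.183; Heyl 35.5-fold). Higher were muscle fibre genes in 31 of 32 with 1 lower (adjusted p = 0.285) and fibro-adipogenic genes in 16 with 4 lower of 20 (0.185). Higher and lower were immune genes in 21 and 1 of 22 (adjusted p = 0.183; C1qb 38.5-fold), and higher alone were erythroid genes in 6 of 6 (0.161; Hbb-b1 110-fold). Higher too were mitochondrially encoded genes in 12 of 12 (adjusted p = 0.185), oxidative phosphorylation genes in 75 of 75 (0.183; Cox7b 47.0-fold) and, except with library sizes from all reads, ribosomal protein genes in 83 and lower in 2 of 86 (0.353). Camera did not call the myogenic differentiation list (9 higher and 4 lower of 13), the cell cycle list (4 and 14 of 19; adjusted p = 0.0536, and 0.0493 without total RNA replicate 2) or the endothelial list (14 and 5 of 20; 15 and 5 over the list alone). The endothelial list (adjusted p = 0.0536) passed with median-of-ratios factors (0.0247), without the filter (0.0446), with a filter of 50 reads (0.0424) and with the fibre, mitochondrial and erythroid lists left out of the normalization (0.0255). The cell cycle list passed without the filter (adjusted p = 0.0452), with a filter of 50 reads (0.0424) and with all groups in 1 fit (0.0499), and the Notch call ended with library sizes from all reads (0.0883). Camera did not call the smooth muscle list (7 and 4 of 13), the Schwann list (4 and 5 of 10) or the tenocyte list (7 and 3 of 10). The median of all genes moved by 0.37 with median-of-ratios factors (7630 higher and 6035 lower), where the Schwann median turned positive. It moved by -1.2 with library sizes from all reads (3217 and 12174), where the medians of the myogenic differentiation, endothelial, smooth muscle and tenocyte lists turned negative.

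The time of labelling was compared next, as labelled RNA of 6 h would be more recent than that gathered over 4 d. Per the labels, injections were 12 h apart for the 1 d and 4 d labels, and no interval is given for 6 h. Labelling time and repeated injection thus change together and cannot be told apart. Unlabelled RNA carried through the pull-down was not tested for here either. Among the largest rises in the 6 h label, Pdk4 stood at 1711 ± 70.3 against 47.6 ± 7.48 RPKM (35.9-fold, adjusted p = 8.08e-13, n = 4 each). Ddit4, an inhibitor of mTOR signalling, stood at 293 ± 41.4 against 10.5 ± 1.38 (26.7-fold). Ucp3 was 21.2-fold higher and Foxo1 (chromosome 3, 52268337 to 52350109), a transcription factor active in fasting, 14.8-fold higher. Among the falls, Camp fell 17.9-fold, Ngp 13.7-fold and S100a9 9.73-fold, all known from neutrophils, and the globin gene Hbb-b1 fell 7.03-fold. Myf5 rose 5.77-fold to 9.40 ± 0.461 RPKM, Myf6 4.11-fold and Cdkn1a 4.33-fold, and Myod1 fell 2.28-fold. Egr1 was 1.63-fold and Hspa1a 1.69-fold higher. Acta1 was 2.02-fold lower, a call that ended with all groups in 1 fit (adjusted p = 0.0542), and Pax7 was under the level needed for a test.

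Of 11975 genes, 6306 were higher and 4317 lower in the 6 h than in the 4 d label, 1634 and 828 by at least 2-fold, and the median was 0.18. Immediate early genes were higher in 23 and lower in 3 of 29 (adjusted p = 0.382 with an estimated correlation), with Klf6 at 5.47-fold, Gadd45g at 5.38-fold, Jun at 4.79-fold and Fos at 3.10-fold. Lower were muscle fibre genes in 32 of 32 (adjusted p = 0.357; Tnni1 3.69-fold), fibro-adipogenic genes in 16 and higher in 2 of 20 (0.357) and erythroid genes in 6 of 6 (0.357). Lower too were ribosomal protein genes in 83 and higher in 1 of 86 (adjusted p = 0.373; Rpl7 2.36-fold) and oxidative phosphorylation genes in 74 and higher in 1 of 75 (0.373). Camera did not call the satellite cell list (16 higher and 6 lower of 23; Chodl 6.75-fold and Sdc4 6.40-fold higher, Itga7 3.39-fold lower), the Notch list (10 and 2 of 16) or the cell cycle list (15 and 3 of 19). Camera did not call the NF-kB list (12 and 3 of 19; Nfkbia 3.61-fold higher), the endothelial list (13 and 3 of 21) or the heat shock list (8 and 7 of 18). Nor did it call the myogenic differentiation list (6 and 6 of 13), the immune list (8 and 8 of 22, median -0.02, mean 0.11) or the smooth muscle list (4 and 6 of 14). Also not called were the Schwann list (3 and 4 of 11; 3 and 3 over the list alone), the tenocyte list (3 and 2 of 8, median 0.04, mean -0.13) and the mitochondrially encoded list (6 and 6 of 12). Without the filter the satellite cell, Notch, cell cycle and endothelial lists passed (adjusted p = 0.0409, 0.0409, 0.00933 and 0.0409). The heat shock list had a median of 0.01 that lay below that of all genes and turned negative with median-of-ratios factors. With library sizes from all reads the median of all genes moved by 0.15, and the medians of the myogenic differentiation, immune, smooth muscle, Schwann and mitochondrial lists turned positive.

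Between 1 d and 4 d of labelling the differences were small: of 11232 genes, 3736 were higher and 2354 lower at 1 d, but 20 and 84 by at least 2-fold, and mean levels correlated at 0.989 across genes. With all groups in 1 fit 526 were higher and 338 lower. Injections were given over more days for the 4 d label, so labelling time and repeated injection cannot be told apart here. Among the largest falls were 4 genes that interferon is known to induce. Isg15, a ubiquitin-like protein (chromosome 4, 156199424 to 156200818), stood at 4.84 ± 0.345 against 27.2 ± 4.71 RPKM (5.13-fold, adjusted p = 1.14e-08, n = 4 each). Ifit3 was 5.20-fold, Ifit1 4.85-fold and Irf7 4.42-fold lower, and Nmrk2, a nicotinamide riboside kinase of muscle, 5.37-fold lower. Pdk4 stood at 303 ± 64.4 against 47.6 ± 7.48 RPKM (6.27-fold higher), Trim63, a ubiquitin ligase of muscle wasting, was 2.86-fold and Cdkn1a 2.56-fold higher. Acta1 stood at 60351 ± 1512 against 60577 ± 1533 RPKM (adjusted p = 0.951) and Myf5 at 1.36 ± 0.271 against 1.26 ± 0.434 (0.620). Hspa1a was 1.5-fold higher, a call that ended with all groups in 1 fit (adjusted p = 0.161), and Pax7 was under the level needed for a test.

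Erythroid genes were lower at 1 d in 6 of 6 (adjusted p = 0.160 with an estimated correlation; Hbb-b1 3.59-fold, Alas2 2.99-fold). Lower too were ribosomal protein genes in 85 of 86 (adjusted p = 0.240; Rps12 1.87-fold), mitochondrially encoded genes in 11 of 12 (0.160; ATP6 2.37-fold) and immune genes in 14 of 22 (0.368; C1qa 1.49-fold). Immediate early genes were higher in 17 and lower in 3 of 27 (adjusted p = 0.362; Gadd45b 1.80-fold, Egr1 1.70-fold, Jun and Fos 1.62-fold). Myogenic differentiation genes were higher in 8 and lower in 2 of 12 (adjusted p = 0.368; Actc1 1.90-fold, Myod1 1.18-fold), endothelial genes in 15 and 1 of 20 (0.361) and tenocyte genes in 7 and 1 of 8 (0.160; Fmod 1.6-fold). Camera did not call the heat shock list (11 higher and 3 lower of 18; 11 and 4 over the list alone; Bag3 1.56-fold higher) or the NF-kB list (1 and 8 of 18). Nor did it call the satellite cell list (6 and 3 of 21; 5 and 2 over the list alone) or the Notch list (5 and 1 of 14; 5 and 0 over the list alone). Also not called were the cell cycle list (4 and 5 of 13) and the muscle fibre list (12 and 7 of 32, median -0.02, mean 0.06). The same went for the fibro-adipogenic list (9 and 5 of 20, median 0.02, mean -0.03; Dpt 2.58-fold lower, Col1a1 1.71-fold higher) and the smooth muscle list (2 and 4 of 13). It went for the Schwann list (2 and 2 of 9; 1 and 2 over the list alone) and the oxidative phosphorylation list (14 and 16 of 75; 12 and 14 over the list alone). The NF-kB list (adjusted p = 0.0758) passed without 4 d replicate 3 or 4 (0.0494 and 0.0412), and the oxidative phosphorylation list without 1 d replicate 1 (0.0122). The heat shock list passed without the filter (adjusted p = 0.00648) and with a filter of 50 reads (0.0261). With all groups in 1 fit the calls of the endothelial list (adjusted p = 0.123), Myod1 (0.511), Actc1 (0.125) and C1qa (0.102) ended. The median of all genes was 0.04 and no scaling moved it by over 0.1, but the cell cycle, smooth muscle and oxidative phosphorylation medians, all within 0.02 of 0, turned positive with library sizes from all reads.

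Stem cells fixed in the animal before isolation were compared with unfixed ones to ask how isolation itself changes their RNA. Fixation, the RNA recovered from fixed cells and the mix of cells sorted may differ as well. A difference therefore need not come from isolation. After fixation Fos stood at 44.1 ± 22.6 (n = 4) against 2258 ± 239 RPKM (n = 3), 54.7-fold lower (adjusted p = 8.54e-06). Egr1 stood at 48.3 ± 13.6 against 3780 ± 771 (79.1-fold) and Atf3 at 5.04 ± 4.78 against 720 ± 247 (172-fold). Fosb was 166-fold and Zfp36, which destabilises cytokine mRNA (chromosome 7, 28376784 to 28379255), 105-fold lower. The heat shock gene Hspa1a was 120-fold and the chemokine genes Cxcl1 and Ccl2 71.7-fold and 49.3-fold lower. Pax7 was 2.20-fold higher, 65.4 ± 15.5 against 29.5 ± 7.96 RPKM (adjusted p = 0.0116), a call that ended without unfixed replicate 1 (0.0516) or 3 (0.0615). Sox8, a transcription factor found in satellite cells, rose 17.2-fold and Cdkn1c 9.58-fold. Myf5 (72.2 ± 23.8 against 93.3 ± 14.7 RPKM) and Myod1 (266 ± 145 against 256 ± 6.44) did not pass the test (adjusted p = 0.297 and 0.762). Jun was 23.5-fold lower. Acta1 stood at 171 ± 134 against 866 ± 799 RPKM (adjusted p = 0.104), and was lower without unfixed replicate 2 (0.0411) and under limma-voom (0.0165).

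In numbers, 1564 genes were higher and 1387 lower after fixation of 12816 tested, 1261 and 1222 by at least 2-fold. Immediate early genes fell in 33 of 34 (34 over the list alone; adjusted p = 0.0721 with an estimated correlation). NF-kB and cytokine genes fell in 21 of 22 (22 over the list alone; adjusted p = 0.0883; Nfkbiz 16.2-fold) and heat shock genes in 11 of 18 (13 over the list alone; 0.206; Dnajb1 30.9-fold, Bag3 14.4-fold). No gene of these 3 lists rose. Endothelial genes fell in 17 of 22 (18 over the list alone; adjusted p = 0.321; Tie1 11.3-fold, Pecam1 7.35-fold) and muscle fibre genes in 9 of 30 (21 with 1 rise over the list alone; 0.480; Myh4 15.8-fold). Lower too were fibro-adipogenic genes in 5 of 20 (adjusted p = 0.470) and tenocyte genes in 4 of 10 (5 over the list alone; 0.388). Ribosomal protein genes rose in 78 of 84 (80 over the list alone; adjusted p = 0.321; Rpl29 4.98-fold) and mitochondrially encoded genes in 7 of 10 (8 over the list alone; 0.321; ND6 10.8-fold). Oxidative phosphorylation genes rose in 56 of 76 (61 with 1 fall over the list alone; adjusted p = 0.321; Uqcr11 4.52-fold) and cell cycle genes in 13 with 1 fall of 26 (16 and 1 over the list alone; 0.385; Cdk1 4.95-fold, Ccnd1 3.25-fold). Satellite cell genes rose in 3 and fell in 8 of 26 (6 and 8 over the list alone), Asb5 15.1-fold and Sdc4 8.81-fold lower. Notch genes rose in 1 and fell in 2 of 16 (0 and 2 over the list alone) and myogenic differentiation genes in 7 and 2 of 16 (7 and 3 over the list alone). Rises and falls numbered 0 and 1 of 21 for immune genes, 0 and 0 of 6 for erythroid genes, 1 and 3 of 14 for smooth muscle genes (1 and 4 over the list alone) and 0 and 1 of 14 for Schwann genes. Camera called none of these 7 lists. The fibro-adipogenic call ended without unfixed replicate 2 or 3 or fixed replicate 1 (adjusted p = 0.0642, 0.0516 and 0.207), and the tenocyte call without unfixed replicate 2 or fixed replicate 3 (0.0910 and 0.0561). The myogenic differentiation list passed without fixed replicate 1 (0.00461), the immune list without unfixed replicate 1 or fixed replicate 1 (0.00378 and 0.0454) and the smooth muscle list without unfixed replicate 1 or fixed replicate 5 (0.00661 and 0.0286). Without unfixed replicate 2, 982 genes were higher and 880 lower, and without unfixed replicate 3, 809 and 718.

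Some transcripts known from other tissues were above every unfixed library in each fixed library, by amounts that differed widely. Mucl2, a secreted gland protein, stood at 94860 RPKM in fixed replicate 1, 2462 in replicate 3, 951 in replicate 4 and 38.2 in replicate 5, against 2.92 to 18.2 in unfixed cells. S100a9, a neutrophil gene, stood at 29.3, 72.0, 670 and 52.9 RPKM, against 0.929 to 4.73 in unfixed cells, and the epithelial keratin gene Krt8 at 111, 13.8, 18.3 and 13.7, against 0.147 to 2.13. Myog stood at 227, 861, 1325 and 1318 RPKM in fixed replicates 1, 3, 4 and 5, all above the 31.7 to 65.7 of unfixed cells, whereas Myod1 stood at 48.1 in fixed replicate 1 and at 326 to 354 in the others. The rise of Mucl2 (adjusted p = 0.0258) did not pass without unfixed replicate 1, 2 or 3 or fixed replicate 3 (0.0554 to 0.102), nor under limma-voom (0.0758).

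**Figure D3:**
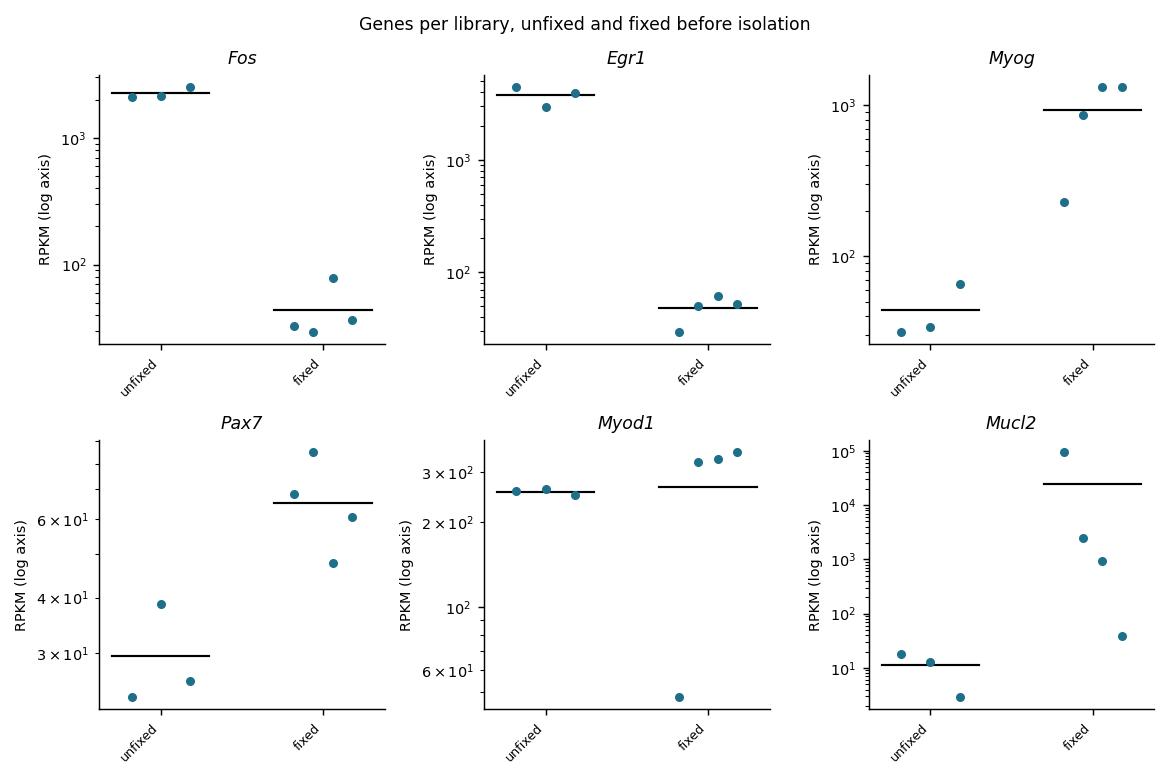
Levels of Fos, Egr1, Myog, Pax7, Myod1 and Mucl2 in unfixed (n = 3) and fixed (n = 4) stem cells, in RPKM on a log axis; points are libraries and lines are group means. Fos averages 44.1 RPKM in fixed and 2258 in unfixed cells, and Mucl2 spans 38.2 to 94860 RPKM among the fixed libraries.

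Whether the same genes stood out in separate comparisons was tested by their overlap, with a one-sided Fisher's exact test over genes tested in both. No library was shared. Genes are not independent, so the p describes the overlap alone. Genes lower after fixation and higher in the isolation label than in the 6 h label numbered 452, against 296 for independent lists (Fisher's exact p = 1.29e-25), among them Cxcl1, Egr1, Ier2, Ppp1r15a, Tnfaip6, Hspa1b, Pxdc1 and Fos. Genes lower after fixation and lower with alpha-amanitin numbered 128, against 126.5 for independent lists (Fisher's exact p = 0.456), among them Slfn5, Elf2, Usp9x and Arl5b. That count was 288 with median-of-ratios factors (Fisher's exact p = 0.00170) and 501 with library sizes from all reads (Fisher's exact p = 3.50e-11). It was 67 and 61 without unfixed replicates 2 and 3 (Fisher's exact p = 0.958 and 0.741), and 66, 83 and 104 without alpha-amanitin replicates 2, 3 and 4 (Fisher's exact p = 0.0451, 0.00132 and 0.00112). Without DMSO replicates 2, 3 and 4 it was 82, 80 and 83 (Fisher's exact p = 0.0119, 0.0141 and 0.0274), and 183, against 248 for independent lists, without alpha-amanitin replicate 1 (Fisher's exact p = 1). Without muscle-enriched genes it was 128, against 160 for independent lists (Fisher's exact p = 0.999). Genes higher in the isolation label than in total RNA and lower with alpha-amanitin numbered 10, against 440 for independent lists (Fisher's exact p = 1), among them Rab27a, P2rx7, Nfatc2ip, Limch1 and the mitochondrial tRNA gene mt-Ty. That count lay between 4 and 78 when single libraries were left out, 78 without alpha-amanitin replicate 1 and 4 without its replicate 2, 3 or 4 or without DMSO replicate 2 or 3. It was 5 without DMSO replicate 4 or total RNA replicate 1 or 2, 6 without total RNA replicate 3 or 4, and 17 without isolation label replicate 3. Without muscle-enriched genes it was 7, against 163 for independent lists. The one-sided test looks for more sharing only and does not measure such a shortfall. Muscle fibre genes were higher in both comparisons, and log2 change fell with gene length in both (rank correlation -0.327 and -0.205). Few shared genes therefore need not reflect transcription during isolation.

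**Figure D4:**
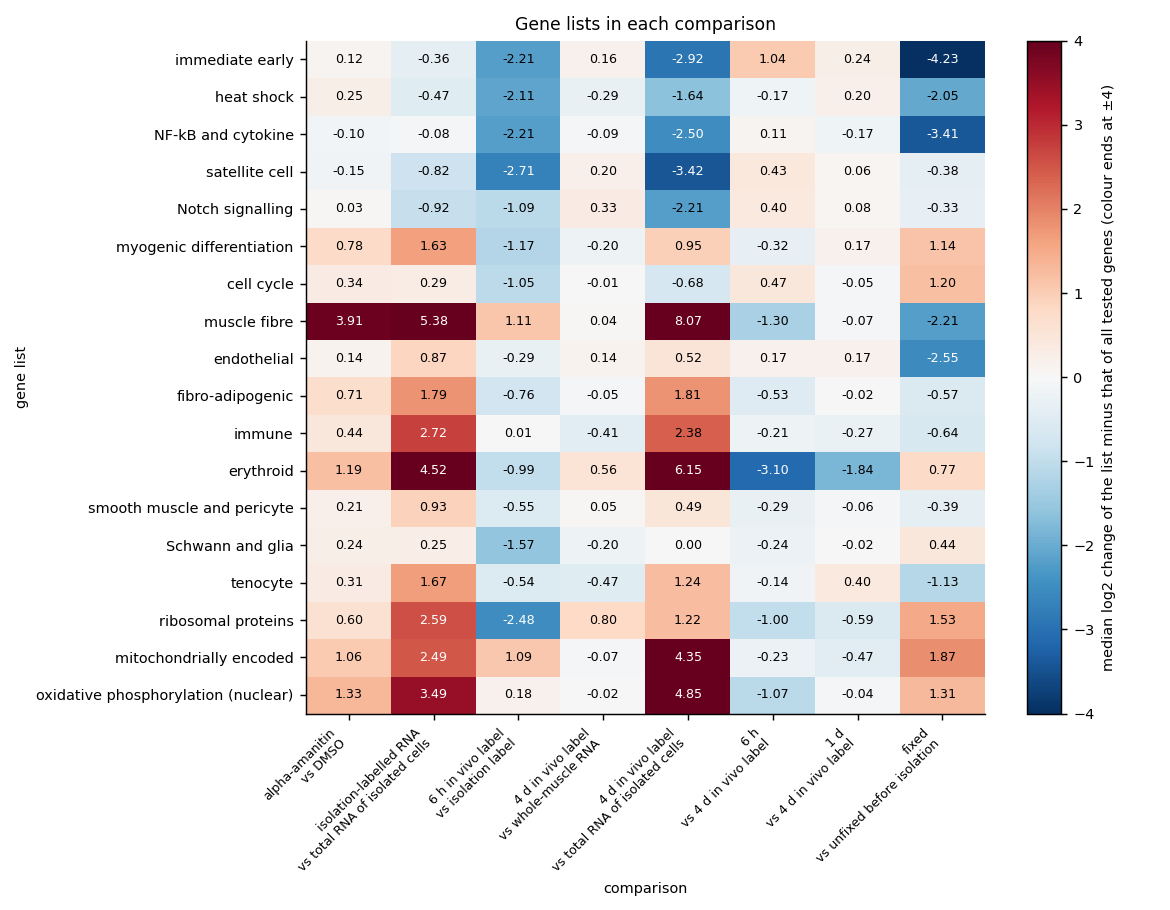
Median log2 change of each of the 18 gene lists minus the median of all tested genes, in the 8 comparisons; the colour scale ends at -4 and 4. The immediate early list lies 4.23 below all genes after fixation and 2.21 below in the 6 h label against the isolation label, and 0.12 above with alpha-amanitin, where its own median turns lower with library sizes from all reads or from mitochondrially encoded genes.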

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

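Of the tests in this part, those of a wrong label and of a swap for alpha-amanitin replicate 1, and all 3 tests of the 4 d label, were chosen after the result was seen. A library was singled out by Dixon's test where its gap to the nearest other of its 4 libraries was too large a share of their range. Of 198 values tested, 18 stood apart, against 9.9 by chance at 1 in 20.

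Mean correlation with the rest of the group was 0.911 for alpha-amanitin replicate 1 (others 0.967 to 0.969) and 0.983 for DMSO replicate 1 (others 0.9903 to 0.9907). The 10 top genes took 8.81% of reads in DMSO replicate 1 (others 8.05 to 8.17%), 23.1% in 1 d replicate 4 (23.3%) and 24.7% in 4 d replicate 1 (24.1 to 24.2%). Recovered reads numbered 87375972 in 6 h replicate 4 (87.38 M; others 30933516 to 36263387), and genes with reads 16964 in isolated-cell replicate 1 (others 16972 to 16973). In 1 d replicate 1, heat shock genes took 0.390% of reads (others 0.378 to 0.379%), satellite cell genes 0.434% (0.455 to 0.459%) and oxidative phosphorylation genes 4.55% (4.09 to 4.14%). In 1 d replicate 4, immediate early genes took 0.106% (others 0.103 to 0.104%) and endothelial genes 0.137% (0.140 to 0.141%). In 6 h replicate 4, satellite cell genes took 0.314% (others 0.330 to 0.332%) and fibro-adipogenic genes 0.244% (0.257 to 0.259%). Immediate early genes took 0.0940% in whole-muscle replicate 4 (others 0.0900 to 0.0902%), NF-kB and cytokine genes 0.0217% in 4 d replicate 2 (0.0209 to 0.0210%), ribosomal protein genes 1.22% in 4 d replicate 4 (1.15 to 1.16%) and endothelial genes 0.281% in isolation label replicate 4 (0.231 to 0.235%).

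Alpha-amanitin replicate 1 stood apart from replicates 2 to 4, and its place was measured on a scale from DMSO (0) to those 3 replicates (1), over called genes that are not muscle-enriched. Its median position was -0.0852. The position rests on the authors' scaling, with factors of 1.54 in replicate 1, 1.25 to 1.66 with DMSO and 0.917 to 0.980 in replicates 2 to 4. It therefore can neither exclude less muscle RNA as the only difference nor tell whether a DMSO library stands under the wrong label. Shares of reads do not use that scaling. Across the alpha-amanitin libraries, NF-kB genes took 0.456 to 0.485% of reads, immediate early genes 3.92 to 5.10% and Schwann genes 0.125 to 0.131%. Across the DMSO libraries these shares were 0.648 to 0.689%, 5.96 to 6.53% and 0.169 to 0.184%. For these lists the values argue against a DMSO library under the wrong label. Heat shock, cell cycle, endothelial, immune and tenocyte shares overlapped. Correlations of replicate 1 were higher with DMSO (0.945 to 0.961) than with replicates 2 to 4 (0.907 to 0.917). Its Gm10800 share, 2.08% of reads, lay near replicates 2 to 4 (2.20 to 3.39%) and not DMSO (0.134 to 0.240%). However, this is 1 gene picked after its values were seen, and in unfixed cells it spans 0.436 to 2.86%. Mucl2, also picked after its values were seen, went the other way. It stood at 7.46 RPKM in replicate 1, 0.347 to 0.456 in replicates 2 to 4 and 4.42 to 6.82 with DMSO. A first test used Acta1, at 1132 RPKM against 16.8 to 35.8 with DMSO, and was set aside after its result was seen, because fibre RNA can enter a library whatever its label. DMSO replicate 1 lay at 0.287 and not near 1, but that position rests on the same scaling. Its NF-kB, immediate early and Schwann shares lay with the other DMSO libraries, which argues against a swap for these lists. No biological explanation was tested.

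Muscle fibre genes and, except with library sizes from mitochondrially encoded genes, ribosomal protein genes were higher with alpha-amanitin, and RNA of muscle fibres mixed into the libraries was tested for both. For the 32 fibre genes the rise divided by the whole-muscle level had an upper over lower quartile of 1.98, as mixing predicts. A mixed share was taken from these genes in RPKM on the authors' scale. Library scaling factors were 1.54 in replicate 1, 0.917 to 0.980 in replicates 2 to 4 and 0.612 to 0.649 in whole muscle. The share is thus not one of reads, and it and the values predicted from it depend on that scaling. It came to 6.30% (1.48% in replicate 1 and 6.92 to 8.47% in the others). That share gives the mitochondrially encoded list a median of 1.04 against 1.34 measured, so library sizes from those genes rest on genes that mixing raises, and it gives 1.47 against 1.61 for oxidative phosphorylation and 1.38 against 1.47 for erythroid genes, but 0.0307 against 1.05 for myogenic differentiation, 0.0551 against 0.99 for fibro-adipogenic and 0.219 against 0.72 for immune genes. For ribosomal genes it gives 0.0253 against 0.87 measured, so mixing does not account for them. They lay 1.43 above genes of like length, a set that leaves out muscle-enriched genes, and 0.60 above all genes, which include them. The median of all tested genes without muscle-enriched ones was -0.07. Among genes that are not muscle-enriched, a trend with gene length thus does not account for the ribosomal rise. Length among muscle-enriched genes was not tested. Mixing gives at least 50% of the rise in 1060 of 4646 higher genes (22.8%), and the inhibitor itself as a cause of the ribosomal rise was not tested.

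The 4 d label lay close to whole-muscle RNA, although the enzyme was meant to act in stem cells. Unlabelled RNA carried through the pull-down as the only source stays open: 2462 genes were at least 2-fold apart between the 6 h and 4 d labels, but these are separate pull-downs with no matching total RNA for each. Label in cells other than satellite cells stays open too: the satellite cell list lay 0.20 above all genes (log2), and unlabelled RNA would give a low value as well. A share of unlabelled RNA beside labelled RNA could not be told from this (correlation 0.955). No biological explanation beyond labelling in other cells was tested.

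Whether the counts of called genes could come from chance was tested with all 35 ways of splitting the libraries of a comparison. For alpha-amanitin, 2 of 35 splits gave as many called genes as the real one (6058, highest other 8747), so this test cannot exclude chance there. The other split sets alpha-amanitin replicate 1 with DMSO replicates 2 to 4. It parts scaling factors of 1.54 to 1.66 from those of 0.917 to 1.25, so its count may follow library scaling, which was not tested. In the other 7 comparisons only 1 of 35, the real split, reached its own count, the smallest share this test can give. Groups that differ in tissue, pull-down or batch would give that too, and replicates may be technical. The test therefore does not show what sets these groups apart. The counts of the real splits were 8843 for isolation label against total RNA, 8188 for 6 h against isolation label, 9586 for 4 d label against whole muscle and 14031 for 4 d label against isolated cells. They were 10623 for 6 h against 4 d and 6090 for 1 d against 4 d, with 0 genes as the highest other in these 6, and 2951 for fixed against unfixed cells, where the highest other was 149.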

How the results depend on the processing

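Library sizes from all reads and tests without muscle-enriched genes were added after the data had been seen. Across all settings but single left-out replicates, those added ones included, 2538 gene results were the same, 23 weaker, 14 stronger and 10 reversed, and of list results 1322 were the same, 9 weaker, 36 stronger and 1 reversed; with 1 replicate left out these were 2110, 26, 2 and 0 for genes and 1104, 8, 22 and 0 for lists. Reversed with alpha-amanitin were Jun under limma-voom (0.36), Egr1 with library sizes from all reads (-0.51) and, with library sizes from mitochondrially encoded genes, Myod1 (-0.72), Egr1 (-1.62), Hspa1a (-0.89), Klf4 (-0.28), Csf1 (-0.46), Chrdl2 (-0.36) and, by the sign of camera, the ribosomal list, whose median stayed 0.50 above all genes. Myod1 also reversed with library sizes from all reads in the isolation label (-0.60) and in the 4 d label against whole muscle (0.11). Counts that moved by over 1.5 times with alpha-amanitin (4646 higher, 1412 lower) were 2243 lower with median-of-ratios factors, 8501 and 3796 with limma-voom, 3125 lower with all groups in 1 fit, 4206 lower with library sizes from all reads, 281 and 13269 with library sizes from mitochondrially encoded genes, and 1259 higher without muscle-enriched genes. For the isolation label (4426 and 4417) they were 7678 lower with library sizes from all reads and 1174 higher without muscle-enriched genes. With library sizes from all reads, 6 h against isolation label gave 2558 and 4883 (5010 and 3178), and 4 d label against isolated cells 3217 and 12174 (6465 and 7566). The 4 d label against whole muscle (3189 and 6397) gave 7489 higher without the filter and 1883 and 4154 with all groups in 1 fit, 6 h against 4 d (4317 lower) gave 7220 lower without the filter, 1 d against 4 d (3736 and 2354) gave 526 and 338 with all groups in 1 fit, and fixation (1564 and 1387) gave 2794 and 2280 with limma-voom. Genes higher in the isolation label and lower with alpha-amanitin (10) were 20 with library sizes from all reads and 3 at 2-fold; genes lower after fixation and with alpha-amanitin (128) were 288 with median-of-ratios factors, 501 with library sizes from all reads and 20 at 2-fold; genes lower after fixation and higher in the isolation label (452) were 300 at 2-fold. Without 1 replicate, alpha-amanitin gave 2317 to 7367 higher and 511 to 3293 lower, fixation 809 to 1821 higher and 718 to 1563 lower, and the first 2 of these overlaps 4 to 78 and 61 to 183. With the replicate number as a block, 1678 and 300 genes were called with alpha-amanitin and 845 were higher after fixation. Calls of Myod1 (adjusted p = 0.113), Myf5 (0.166), Il6 (0.0957) and Rbpj (0.0505) with alpha-amanitin and of Actc1 after fixation (0.0520) ended with it, and Acta1 passed after fixation (0.00532). The same-number correlations ran from -0.591 to 0.236 and not every sample correlated best with its own number. For every changed result the cause was not tested, apart from fewer libraries or genes where these were left out. DESeq2 was planned for whole counts and was not run. Depth limits the isolation label most, at 2321903 to 7742378 reads per library.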

Other observations

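Neat1, a long noncoding RNA of the nucleus, stood at 95.7 ± 5.29 RPKM in the 6 h label, 30.6 ± 2.07 at 1 d, 38.02 ± 1.035 at 4 d, 35.4 ± 1.79 in whole muscle and 9.16 ± 0.209 in isolated cells (n = 4 each). Gm10800 stood at 287510 ± 48093 RPKM in the 6 h label, 13291 ± 1084 at 1 d, 33916 ± 6192 at 4 d and 2562 ± 115 in whole muscle.

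Isg15, which interferon is known to induce, stood at 49.2 ± 15.8 RPKM in the isolation label, 27.2 ± 4.71 at 4 d, 4.84 ± 0.345 at 1 d, 4.17 ± 0.534 at 6 h, 7.87 ± 0.906 in whole muscle and 5.05 ± 0.138 in isolated cells. In cells isolated with DMSO it stood at 15.9 ± 3.38 RPKM and with alpha-amanitin at 19.99 ± 5.37 (n = 4 each). It stood at 29.2 ± 13.4 in unfixed (n = 3) and 8.004 ± 2.032 in fixed cells (n = 4). Fam132b stood at 252 ± 66.0 RPKM in the isolation label, 799 ± 81.9 with alpha-amanitin and 687 ± 57.3 with DMSO, against 0.297 ± 0.0446 in whole muscle. Camp, a neutrophil gene, ranged from 3.04 to 371 RPKM among fixed libraries.

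The rank correlation of log2 change with gene length across genes was -0.205 for alpha-amanitin, -0.327 for isolation label against total RNA, 0.194 for 6 h against isolation label, 0.0235 for 4 d label against whole muscle and -0.176 for 4 d label against isolated cells. It was 0.312 for 6 h against 4 d, 0.280 for 1 d against 4 d and -0.117 for fixed against unfixed cells.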
